A study of Mus musculus with 9 samples.

How the data were processed

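RNA was measured by sequencing in BV2 cells, an immortalized mouse microglial line, that were untreated or had received bacterial lipopolysaccharide (LPS, 200 ng/ml) for 1 h or 12 h, with 3 libraries per group and 9 in all. Per the labels, total RNA was extracted with TRIzol and libraries were made with a TruSeq Stranded mRNA kit. The submitters' notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq without versions or roles. They also name GRCh38, a human genome build, although the genes carry mouse symbols, so the build behind the values is unclear and no gene position from the notes was used.

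The authors deposited 1 table of FPKM (fragments scaled by transcript length and library size) per gene in the 9 libraries, with no further scaling stated. Per the file headers, the table also holds a p-value and a q-value for each gene, a score that ranks the genes, and a flag. The test behind these deposited columns is not stated. The flag is 1 in all listed genes and the highest deposited q-value is 0.09993, so the listed genes had been selected on a difference among these same samples. The deposited p-value equals 1 minus (1 minus q-value) raised to the rank, within 1%, in 100% of the 4377 genes where this could be computed, and 3146 genes have a deposited p-value of at least 0.5. Those columns were therefore not used to call genes. Genes outside the table were not analysed here.

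FPKM values were compared as log2(FPKM + 1), so a pseudocount of 1 shrinks the differences of genes near 0. Genes with a mean FPKM of at least 1 over the 9 libraries were tested, which kept 5643 and left out 819. Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with a moderated spread that follows the level (eBayes with trend), and 3 contrasts were taken from that fit together with a moderated F test over the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called changed at an adjusted p under 0.05; counts are also given with a log2 difference of at least 1 in size. Because the tested genes were selected on these samples, the adjusted p-values do not give a false discovery rate over the transcriptome.

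The groups, tests, alternatives, rule for named genes and 30 gene lists (547 entries) were chosen before the data were examined. Lists with at least 3 tested members, 22 in number, were tested with limma's camera at its preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Camera compares a list with the other listed genes, which were themselves selected for changing. Counts of list members cover tested genes only, and leave out members missing from the table or below the filter. Tested were 10 of 19 chemokine members, 20 of 28 inflammatory effectors and 13 of 19 antigen presentation members. For homeostatic microglia it was 13 of 23 and for oxidative phosphorylation 4 of 27. Named genes are the 10 largest increases and 10 largest decreases per contrast among changed genes whose 3 libraries in 1 group all lie above the 3 of the other, with a mean FPKM of at least 5 in the higher group and an assigned gene name, together with examples of each list taken in order of the size of the log2 difference, and the genes in the title of the series. Some members that moved against their list were named as well, chosen after their values were seen. Time classes were formed from the 3 contrasts at a log2 difference of at least 1; Cd83, Egr3 and Nr4a1 met the rules of both an early transient rise and a late fall, and were counted under the first, a choice made after their values were seen.

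The fit was tested on simulated data with 5643 genes of which 200 were changed. A log2 difference of 0.1 was recovered in 0% of the changed genes, 0.3 in 80.5% to 86% over the 3 contrasts, and 1 in 100%. False calls were at most 6.5% of calls. In the data 3330 to 4823 genes were called per contrast, far more than the 200 changed here. The adjusted threshold is less strict when more genes change, so these shares do not carry over to the data.

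The table gives no read counts. In genes with an FPKM below 0.5 the values fall on multiples of a smallest step: 88.4% of 172 such values lay within 2% of a whole multiple, against 13.4% when shifted at random. The steps give relative depths of the libraries from 0.9046 to 1.0581, and 15 genes with 1 transcript give a rough depth of 18600000 fragments (quartiles 11900000 and 21300000). These figures cover counting error only and the exact depth is unknown.

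The alternatives were pseudocounts of 0.1 and 0.5, no filter on level, a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, eBayes without trend, array weights, fits of only the 6 libraries compared, the library number as a block, and leaving out each library in turn. Adjustment over the 21878 genes that the deposited ranks imply was added after seeing the data. Tests of other lists, 3′ UTRs and gene spans used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, with GENCODE vM21 and RefSeq genes on GRCm38.p6; bootstrap intervals used 10000 draws and permutation tests up to 100000 permutations. Plots were drawn with matplotlib 3.10.9.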

Results

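Transcript levels were measured in BV2 mouse microglial cells without LPS (0 h) and after 1 h or 12 h with LPS, a component of the outer membrane of Gram-negative bacteria that activates Toll-like receptor 4. Each group had 3 libraries. The title of the series puts the question of how the kinase PLK2 takes part in microglial activation, together with the chaperone HSP90α and the kinase IKKβ. The libraries had relative depths from 0.9046 to 1.0581, estimated from the steps in low FPKM values against untreated library 1. These estimates rest on 5 to 7 genes for each 12 h library and on 13 to 24 for each of the others. The listed FPKM values of the libraries summed to 195872 to 198075 in untreated cells, 203515 to 205413 at 1 h and 223720 to 228207 at 12 h. The sums thus differed between the groups without overlap. The listed genes, 5643 of them tested and 819 below the filter on level, had been selected on a difference among these samples, so every count below describes genes chosen to differ, and lists were compared with other genes chosen in that way.

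Libraries of 1 group were nearly alike across genes, with Pearson correlations of log2(FPKM + 1) from 0.9981 to 0.9986, against 0.9241 to 0.9698 between groups; these are correlations across genes, which are not independent replicates. The first principal component held 70.7% of the variance and the second 26.4%. The spread between libraries of a group was 1.42 to 2.25 times the variance that counting alone gives, over 319 genes with 1 transcript. That ratio rests on the rough depth of 18600000 fragments (quartiles 11900000 and 21300000). A lower depth would make it smaller, so how far the spread exceeds counting is uncertain. Library numbers did not pair the libraries across groups: correlations of residuals between libraries of the same number ran from -0.067 to 0.128. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. In all, 5324 of 5643 tested genes differed among the 3 groups (limma F test).

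Plk2, a stress-responsive polo-like kinase, stood at 13.04 ± 0.722 FPKM in untreated cells (SD, n = 3, as throughout), 120.3 ± 3.83 at 1 h and 40.2 ± 2.97 at 12 h. Its log2 difference from untreated cells was 3.11 at 1 h and 1.55 at 12 h, and it fell by 1.56 between 1 h and 12 h (adjusted p = 1.62e-12). Plk3 rose from 2.23 ± 0.244 to 7.43 ± 0.61 FPKM at 1 h and stood at 7.96 ± 0.272 at 12 h. Its 12 h and 1 h levels differed by 0.09 on the log2 scale, which did not pass the test (adjusted p = 0.194), although without 1 h library 3 it did (0.15, adjusted p = 0.0466). Plk4, which controls centriole duplication, rose by 0.35 at 1 h and had a log2 difference of -0.11 at 12 h that did not pass (adjusted p = 0.228), although without untreated library 1 it did (-0.20, adjusted p = 0.0422). Hsp90aa1, which encodes HSP90α, stood at 619 ± 27.4, 613 ± 12.8 and 674 ± 23.7 FPKM. Its log2 difference was -0.01 at 1 h (adjusted p = 0.726) and 0.12 at 12 h (adjusted p = 0.00407). Under quantile normalization the 12 h value was -0.05 (adjusted p = 0.269) and the 12 h versus 1 h value turned from 0.14 to -0.01, so its direction at 12 h depends on the scaling. Ikbkb, which encodes IKKβ, and Plk1 were not analysed here.

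**Figure D1:**
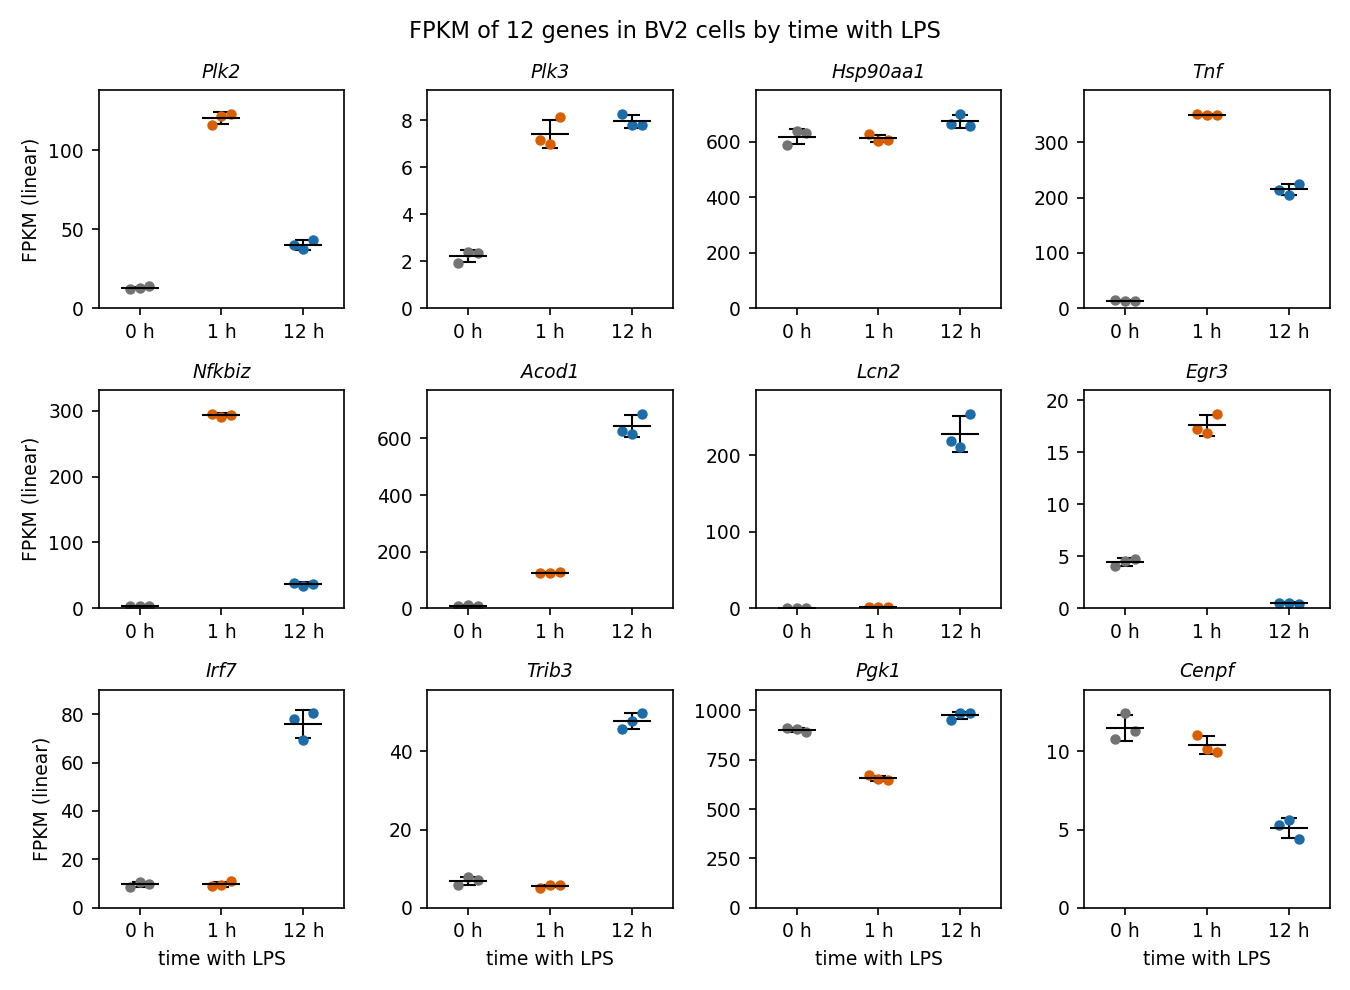
FPKM on a linear axis of 12 genes against time with LPS; points are single libraries, bars the mean and SD of 3 libraries. Plk2 reached 120.3 FPKM at 1 h and 40.2 at 12 h, while Lcn2 was at 0.366 FPKM without LPS, 1.56 at 1 h and 227.8 at 12 h.

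The comparison of 1 h with untreated cells addresses the early response to LPS. Within 1 h, 18 of 19 genes for subunits and feedback regulators of NF-κB, the transcription factor family that drives inflammatory genes, rose, with 10 of 11 cytokine genes and 7 of 10 chemokine genes. With an estimated correlation these lists had adjusted p = 0.0231, adjusted p = 0.1 and adjusted p = 0.1. Nfkbiz, an atypical IκB protein, went from 3.37 ± 0.356 to 293.5 ± 2.62 FPKM, a log2 difference of 6.08. Chemokine genes Cxcl2 (5.59), Cxcl10 (5.23) and Ccl4 (3.98) and the cytokine gene Tnf (4.59; from 13.6 ± 0.716 to 349 ± 1.51 FPKM) followed. The largest decreases were smaller: Ier5l fell by 2.23 and Ddit4, an inhibitor of mTORC1 signaling, fell by 2.08, from 32.9 ± 0.99 to 7.04 ± 0.292 FPKM. Other large increases were those of Gdf15 (3.91), Acod1 (3.75), which makes itaconate, Gpr84 (3.39), Ccrl2 (3.32) and Nfkbia (3.23), which encodes IκBα. Other large decreases were those of Ppp1r3b (-1.62), Arg1 (-1.41), Bhlhe41 (-1.38), Hyal1 (-1.34), Osgin1 (-1.34), Selenbp1 (-1.28), Cd300lb (-1.25) and Gpr183 (-1.24).

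Of 21 tested immediate early genes, 19 rose and 2 fell at 1 h, with a median log2 difference of 1.69 (adjusted p = 9.67e-18; adjusted p = 0.0231 with an estimated correlation). The largest were Nr4a1 (2.88), Maff (2.64), Junb (2.54) and Btg2 (2.40). The 2 that fell were Klf2 (-0.60), which restrains inflammatory genes, and Fos (-0.27). The call for Fos was lost under quantile normalization (adjusted p = 0.0976), with adjustment over the implied genes (adjusted p = 0.0595), and without untreated library 3 (-0.15, adjusted p = 0.0782) or 1 h library 1 (-0.23, adjusted p = 0.0621). Of 19 genes for NF-κB subunits and feedback, 18 rose and 1 did not pass, with a median of 1.09 (adjusted p = 1.85e-17; adjusted p = 0.0231 with an estimated correlation). Besides Nfkbiz and Nfkbia these included Tnfaip3 (2.77) and Zc3h12a (2.71). Among 11 cytokine genes, 10 rose and 1 fell, with a median of 1.31 (adjusted p = 4.33e-08; adjusted p = 0.1 with an estimated correlation). After Tnf the largest were Il1b (2.83), Tnfsf9 (2.48) and Osm (1.73), and Il15 fell by 0.51. Among 10 chemokine genes, 7 rose, 1 fell and 2 did not pass, with a median of 1.85 (adjusted p = 9.04e-07; adjusted p = 0.1 with an estimated correlation). Ccl3 rose by 2.39 and Ccl6 fell by 0.28. Of 20 inflammatory effectors, 16 rose, 2 fell and 2 did not pass, with a median of 0.95 (adjusted p = 4.39e-12; adjusted p = 0.1 with an estimated correlation). Nlrp3 (3.16), an inflammasome sensor, Tlr2 (2.85) and Saa3 (2.72) followed Acod1, while Nos2 (-0.36), the inducible nitric oxide synthase, and Cd86 (-0.24) fell. Nos2 was near the floor in both groups, at 0.762 ± 0.189 FPKM in untreated cells and 0.372 ± 0.112 at 1 h.

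The 3 tested polo-like kinase genes all rose, with a median of 1.38 (adjusted p = 0.00126; adjusted p = 0.1 with an estimated correlation). Of 16 genes of TLR4 and IKK signaling, 9 rose, 4 fell and 3 did not pass, against 11 and 4 when adjusted over the list alone, with a median of 0.11 (adjusted p = 0.0112; adjusted p = 0.161 with an estimated correlation). Cd14, the LPS co-receptor, rose by 1.53, Irak2 by 1.07, Ikbke by 0.87 and Map3k8 by 0.82, and the adaptor gene Ticam2 fell by 0.60. Of 15 genes of cholesterol synthesis and uptake, 13 rose and 2 did not pass, with a median of 0.37 (adjusted p = 1.77e-06; adjusted p = 0.1 with an estimated correlation), among them Insig1 (0.91), a brake on sterol synthesis, and Hmgcs1 (0.54). The glycolysis list went the other way: 17 of 19 fell, 1 rose and 1 did not pass, with a median of -0.25 (adjusted p = 4.14e-06; adjusted p = 0.1 with an estimated correlation). Egln3 (-1.18), an oxygen sensor rather than a glycolytic enzyme, Pfkp (-0.54), Pgk1 (-0.46) and Pdk1 (-0.36), which restrains pyruvate oxidation, led the decreases, and Hif1a rose by 0.23. Of 19 apoptosis and survival genes, 10 rose, 5 fell and 4 did not pass, with a median of 0.65 (adjusted p = 0.00223; adjusted p = 0.1 with an estimated correlation). Those that rose work in opposite directions: Cflar (1.86) blocks death receptor signaling, Gadd45a (1.62) responds to stress, and Fas (1.31) and Bcl2l11 (1.25) promote cell death. With a mean FPKM of at least 5, the median of this list was 0.02 and its call was lost (adjusted p = 0.0622).

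Smaller shifts were found in the S phase list, where 11 of 22 rose (7 when adjusted over the list alone) and none fell, with a median of 0.07 (adjusted p = 0.0047; adjusted p = 0.432 with an estimated correlation). Ccne2 (0.28), Rrm2 (0.28) and Mcm10 (0.27) led, and quantile normalization ended the call (median 0.02, adjusted p = 0.191). Among 14 heat shock chaperones, 8 rose, 2 fell and 4 did not pass, with a median of 0.08 (adjusted p = 0.0433; adjusted p = 0.413 with an estimated correlation), led by Hspa5 (0.35) and Dnajb1 (0.35). That call was lost with a mean FPKM of at least 5 (adjusted p = 0.0951), under quantile normalization (median 0.02, adjusted p = 0.541), with array weights (0.0501), and without untreated library 1 (0.11) or 1 h libraries 1 (0.0684) or 2 (0.0551). The remaining lists were not called at 1 h: interferon-stimulated genes (6 of 32 rose and 7 fell, 3 and 3 when adjusted over the list alone; median -0.02, adjusted p = 0.664), antigen presentation (3 of 13 rose and 4 fell, adjusted p = 0.747), homeostatic microglia (2 of 13 rose and 7 fell, adjusted p = 0.21) and alternative activation (3 of 5 fell, adjusted p = 0.268). Nor were G2/M (2 of 23 rose and 6 fell, adjusted p = 0.747), cholesterol efflux (4 of 7 fell, adjusted p = 0.112) and oxidative phosphorylation (1 of 4 rose and 2 fell, adjusted p = 0.747). The same held for NRF2 targets (5 of 15 rose and 3 fell, adjusted p = 0.664), lysosome (1 of 16 rose and 8 fell, adjusted p = 0.168, but called lower under quantile normalization with a median of -0.12 and adjusted p = 0.016) and the unfolded protein response (8 of 20 rose and 6 fell, adjusted p = 0.236). In the interferon, antigen presentation, NRF2 and unfolded protein lists the median, mean and test differed in sign. Unless another count is given, counts adjusted over the list alone equaled those over all genes, here and at 12 h.

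At 1 h, 1361 genes were higher and 1969 lower than in untreated cells, and at a difference of at least 2-fold in FPKM + 1, 122 were higher and 33 lower. The count of 33 was 71 with a pseudocount of 0.1 and 20 with a mean FPKM of at least 5. Without a filter on level the median was 0.46 for chemokines, 0.68 for cytokines and 0.43 for apoptosis and survival; with a pseudocount of 0.1 it was 2.29 for cytokines and 1.52 for inflammatory effectors (1.53 with a mean FPKM of at least 5), and Ccrl2 (5.29), Il1b (5.03), Fas (3.04) and Nos2 (-0.87) moved too. Without 1 h library 3, Il15 had a difference of -0.34. No untreated cells were taken at 1 h or 12 h, so LPS and time in culture changed together.

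The comparison of 12 h with untreated cells addresses the late response. Lcn2, which encodes a protein that binds bacterial siderophores, went from 0.366 ± 0.218 to 227.8 ± 23.3 FPKM (log2 difference 7.39), and Il6 from 0.106 ± 0.0776 to 42.2 ± 8.75 FPKM (5.27). Acod1 reached 644 ± 38.6 FPKM (6.10). Of the fixed lists, 31 of 32 interferon-stimulated genes rose, while 22 of 23 G2/M genes and 12 of 13 homeostatic microglia genes fell. With an estimated correlation these lists had adjusted p = 0.0979, adjusted p = 0.183 and adjusted p = 0.0979. Ccl7 (6.21), Csf3 (6.13), Saa3 (6.06), Cxcl2 (5.71), Ccl12 (4.65), Ccl2 (4.51) and Ccl5 (4.01) made up the rest of the 10 largest increases. The 10 largest decreases were those of Selenbp1 (-2.77; from 50.1 ± 2.07 to 6.54 ± 0.804 FPKM), Cytip (-2.62), Gpr183 (-2.57), a receptor for oxysterols, Lrrc14b (-2.47), Ltc4s (-2.42), which makes leukotriene C4, Abca9 (-2.39), Ephx1 (-2.37), Mxd4 (-2.23), St6gal1 (-2.20) and Abcd2 (-2.15).

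Of 32 interferon-stimulated genes, 31 rose at 12 h with a median of 1.66 (adjusted p = 1.03e-12; adjusted p = 0.0979 with an estimated correlation). Isg15 (3.57), Irf7 (2.85), Rsad2 (2.82) and Oasl2 (2.64) led, and Irf1 had a log2 difference of 0.09 that did not pass (adjusted p = 0.153), although it passed under quantile normalization (adjusted p = 0.0224) and without untreated library 1 (adjusted p = 0.0396). All 20 tested inflammatory effectors rose, with a median of 1.74 (adjusted p = 6.33e-10, and adjusted p = 0.0979 with an estimated correlation). Nos2 (3.51) and Ptgs2 (3.38) followed Lcn2, Acod1 and Saa3. All 10 tested chemokine genes rose, with a median of 3.95 (adjusted p = 8.07e-07, and adjusted p = 0.127 with an estimated correlation). Of 11 cytokine genes, 9 rose and 2 fell, with a median of 2.95 (adjusted p = 0.000442; adjusted p = 0.198 with an estimated correlation), and Il1rn (4.0), which encodes an antagonist of interleukin-1, rose beside Tnf (3.88) and Il1b (2.98). Il15 fell by 1.02. Of 19 NF-κB subunit and feedback genes, 18 rose, with a median of 1.13 (adjusted p = 3.4e-08; adjusted p = 0.0979 with an estimated correlation), led by Nfkbiz (3.10), Zc3h12a (2.59), Bcl3 (2.59) and Socs3 (2.42). All 13 tested antigen presentation genes rose, with a median of 0.45 (adjusted p = 0.000168, and adjusted p = 0.183 with an estimated correlation). H2-T23 (1.02), Tapbp (0.92), Tap1 (0.80) and Cd74 (0.80) led.

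Of 20 genes of the unfolded protein response, 19 rose, with a median of 0.85 (adjusted p = 3.99e-08; adjusted p = 0.0747 with an estimated correlation). The largest were Trib3 (2.62), Chac1 (2.07), Ddit3 (1.78), which encodes the stress factor CHOP, and Herpud1 (1.58), and Xbp1 had a log2 difference of -0.07 that did not pass (adjusted p = 0.113). It passed as lower under quantile normalization (-0.24, adjusted p = 5.02e-05) and without untreated library 2 (adjusted p = 0.048) or 12 h library 3 (adjusted p = 0.0363). Of 15 NRF2 targets, 13 rose and 2 fell, with a median of 0.75 (adjusted p = 2.77e-05; adjusted p = 0.175 with an estimated correlation). Slc7a11 (3.24), a cystine transporter, Sqstm1 (1.41), Fth1 (1.23) and Srxn1 (1.17) led. Fth1, the ferritin heavy chain gene, had the highest FPKM in all 9 libraries (rank 1), and quantile normalization, which gives the top gene of every library 1 value by construction, set its difference to 0. The 2 that fell were Gclc (-0.62), which makes the rate-limiting enzyme of glutathione synthesis, and Osgin1 (-0.17, adjusted p = 0.0279). The call for Osgin1 was lost under quantile normalization (adjusted p = 0.182), with adjustment over the implied genes (0.108), and without untreated libraries 1 (-0.10, adjusted p = 0.156) or 3 (0.0565) or 12 h libraries 1 (0.051) or 2 (0.117). Of 19 apoptosis and survival genes, 15 rose and 2 fell, with a median of 0.37 (adjusted p = 0.000913; adjusted p = 0.0979 with an estimated correlation). Bcl2a1d (2.34), Bcl2a1b (2.05) and Bcl2l1 (1.45), all of which protect cells from death, rose with Gadd45a (2.02), and Pmaip1, which promotes death, fell by 1.22. Bcl2a1d and Bcl2a1b are near-identical copies whose reads are hard to assign. Of 21 immediate early genes, 16 rose and 3 fell, with a median of 0.72 (adjusted p = 0.000913; adjusted p = 0.159 with an estimated correlation). Fosl1 (2.45), Ier3 (2.04) and Maff (1.33) rose, and Egr3 (-1.90), Nr4a1 (-1.21) and Klf2 (-0.97) fell.

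Of 23 G2/M genes, 22 fell and 1 did not pass at 12 h, with a median of -0.49 (adjusted p = 8.07e-07; adjusted p = 0.183 with an estimated correlation). Cenpf (-1.04), Nusap1 (-1.02), Mki67 (-0.94) and Ccnb2 (-0.87) led, and Aurka had a difference of -0.02 that did not pass (adjusted p = 0.583; 0 without untreated library 3), but passed as lower under quantile normalization (-0.17, adjusted p = 0.000189). Of 13 homeostatic microglia genes, 12 fell and 1 rose, with a median of -0.56 (adjusted p = 0.000831; adjusted p = 0.0979 with an estimated correlation). Mertk (-1.40), a receptor for dying cells, Entpd1 (-1.21) and Mef2c (-1.08) led the decreases, and Selplg rose by 0.18 (adjusted p = 0.0127; 0.058 without untreated library 2). Of 7 tested members of the cholesterol efflux list, 6 fell, with a median of -0.45 (adjusted p = 0.0162, and adjusted p = 0.143 with an estimated correlation). This list also holds genes that do not themselves export cholesterol, Mylip and Scd2 among them. Apoe fell by 1.18, from 647 ± 45.8 to 284 ± 8.66 FPKM, Mylip by 1.08, Abcg1 by 0.58 and Scd2 by 0.45. Not called at 12 h were the lists of heat shock chaperones (9 of 14 rose, adjusted p = 0.0594), S phase (5 of 22 rose and 14 fell, adjusted p = 0.0735), polo-like kinases (2 of 3 rose, adjusted p = 0.114) and oxidative phosphorylation (3 of 4 fell, adjusted p = 0.114). Glycolysis (13 of 19 rose and 6 fell, adjusted p = 0.23), lysosome (10 of 16 rose and 5 fell, adjusted p = 0.309), TLR4 and IKK signaling (8 of 16 rose and 6 fell, adjusted p = 0.342), alternative activation (2 of 5 rose and 3 fell, adjusted p = 0.665) and cholesterol synthesis (5 of 15 rose and 8 fell, adjusted p = 0.915) were not called either. The lysosome median, mean and test differed in sign.

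At 12 h, 2318 genes were higher and 2293 lower than in untreated cells, and 256 and 155 at a difference of at least 2-fold. The count of 155 was 306 with a pseudocount of 0.1 and 97 with a mean FPKM of at least 5. Without a filter on level the median was 0.80 for cytokines and 0.32 for immediate early genes, and under quantile normalization it was 0.47 for NRF2 targets. A pseudocount of 0.1 moved Il1b to 5.19, Egr3 to -3.04, Mertk to -2.54 and Nr4a1 to -1.88. The S phase list was called lower with a mean FPKM of at least 5 (adjusted p = 0.0342) and under quantile normalization (adjusted p = 0.0112), under which oxidative phosphorylation was also called lower (adjusted p = 0.0192), and heat shock chaperones were called higher with no filter (adjusted p = 0.049) and without untreated library 3 (adjusted p = 0.0455).

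**Figure D2:**
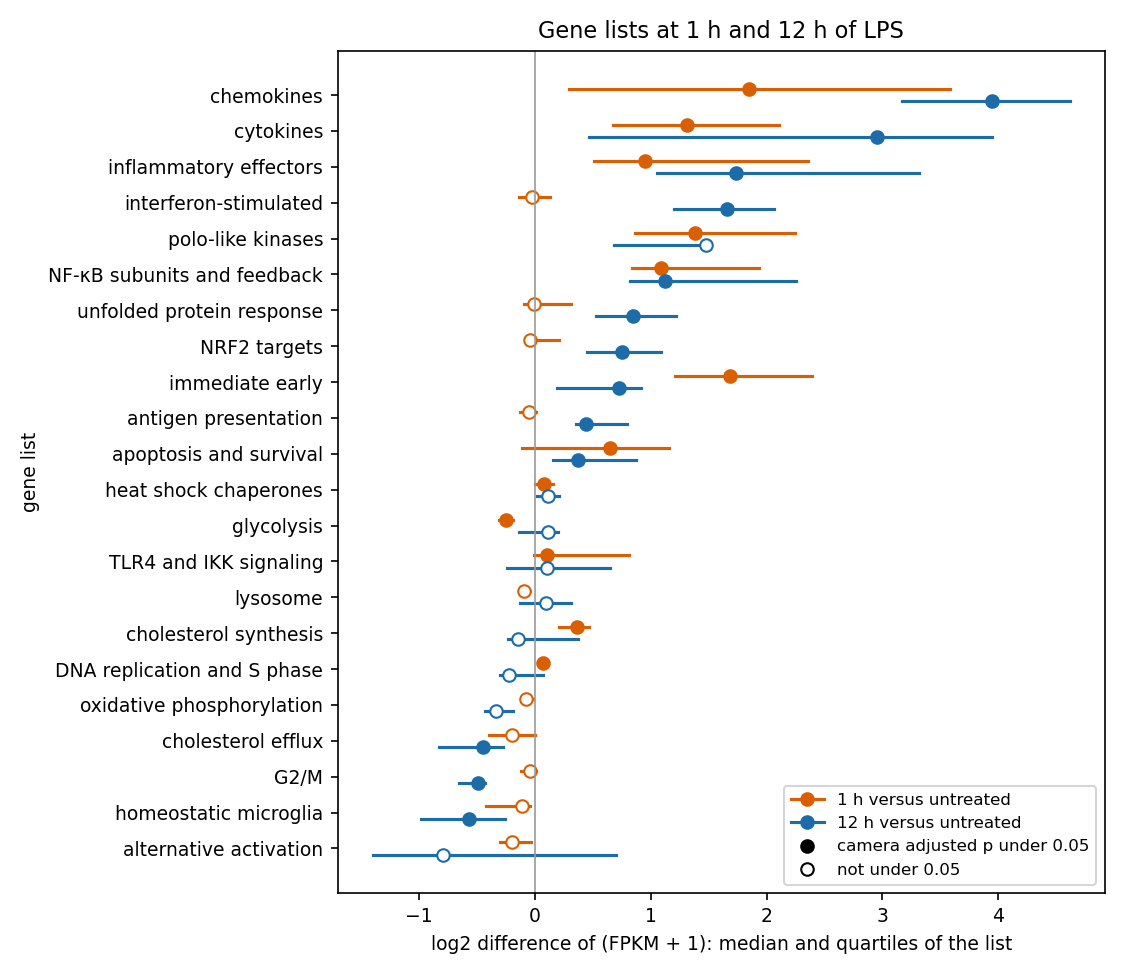
Median (point) and quartiles (line) of the log2 difference in FPKM + 1 from untreated cells for 22 gene lists at 1 h and 12 h; filled points have a camera adjusted p under 0.05 at the preset correlation. The interferon-stimulated list had a median of -0.02 at 1 h and 1.66 at 12 h.

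The comparison of 12 h with 1 h tests directly which responses differ between the times. Between 1 h and 12 h most immediate early genes fell and most interferon-stimulated genes rose (19 of 21 and 31 of 32; adjusted p = 0.121 for each list with an estimated correlation). Nr4a1 went from 28.9 ± 1.6 to 0.762 ± 0.0927 FPKM (log2 difference -4.09), and Egr3 (-3.67), Cd83 (-3.50) and Nfkbiz (-2.98) fell as well. Lcn2 (6.48), Csf3 (5.15), Ccl7 (4.60) and Ccl12 (4.56) rose most. Nos2, which had been near the floor at 1 h (0.372 ± 0.112 FPKM) and in untreated cells (0.762 ± 0.189), rose by 3.87 to 19.1 ± 1.99 FPKM. Il6 (3.78), Pilra (3.50), Pim2 (3.45), Saa3 (3.34) and Ccl5 (3.21) completed the 10 largest increases, and Rasgef1b (-2.90), Btg2 (-2.27), Ltc4s (-2.24), Tlr2 (-2.20), Abca9 (-2.17) and St6gal1 (-2.13) the 10 largest decreases. Cxcl2 and Gdf15 stayed high: Cxcl2 had a log2 difference of 0.12 that did not pass (adjusted p = 0.449; -0.08 without 12 h library 3, adjusted p = 0.519), and Gdf15 fell by 0.17 (adjusted p = 0.0457), a call lost under 9 alternatives, with -0.10 (adjusted p = 0.217) without 12 h library 2.

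Immediate early genes fell in 19 of 21 cases, with a median of -1.02 (adjusted p = 2.66e-06; adjusted p = 0.121 with an estimated correlation). Fosl1 (1.24) and Fos (0.52) rose. Interferon-stimulated genes rose in 31 of 32 cases, with a median of 1.66 (adjusted p = 1.93e-12; adjusted p = 0.121 with an estimated correlation), led by Isg15 (2.93), Irf7 (2.83) and Oasl2 (2.51), and Irf1 fell by 1.17. The unfolded protein list rose in 19 of 20 genes, with a median of 0.81 (adjusted p = 1.8e-07; adjusted p = 0.084 with an estimated correlation), led by Trib3 (2.89) and Chac1 (1.76). NRF2 targets rose in 14 of 15 cases, with a median of 0.68 (adjusted p = 4.22e-06; adjusted p = 0.26 with an estimated correlation), led by Slc7a11 (2.33) and Hmox1 (1.57), which degrades heme. Of 19 glycolysis genes, 17 rose and 2 fell, with a median of 0.35 (adjusted p = 0.000179; adjusted p = 0.26 with an estimated correlation). Under quantile normalization that median was 0.19, and the median against untreated cells turned from 0.11 to -0.13. Pfkm (-1.07) and Pdk1 (-0.32) fell, and Slc2a1 (0.99), the glucose transporter gene, and Hk2 (0.62) rose. Cholesterol synthesis fell in 10 of 15 genes and rose in 2, with a median of -0.32 (adjusted p = 0.0191; adjusted p = 0.403 with an estimated correlation), led by Insig1 (-1.17) and Hmgcs1 (-1.10). Antigen presentation rose in 12 of 13 genes (median 0.45, adjusted p = 0.000689; adjusted p = 0.338 with an estimated correlation), led by H2-T23 (1.24) and Tap1 (0.93). G2/M genes fell in 22 of 23 cases (median -0.48, adjusted p = 3.15e-06; adjusted p = 0.338 with an estimated correlation), led by Nusap1 (-1.03) and Cenpf (-0.90). S phase genes fell in 17 of 22 cases and rose in 1 (median -0.29, adjusted p = 0.00272; adjusted p = 0.403 with an estimated correlation), led by Mcm7 (-0.58) and Dut (-0.48). Homeostatic microglia genes fell in 10 of 13 cases and rose in 3 (median -0.40, adjusted p = 0.0181; adjusted p = 0.279 with an estimated correlation), led by Rhob (-1.88), which had risen by 1.62 at 1 h, and Mertk (-1.31).

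Chemokine genes rose in 7 of 10 cases and fell in 2 (median 1.00, adjusted p = 0.0173; adjusted p = 0.403 with an estimated correlation), Cxcl10 (-1.35) being the larger fall. Inflammatory effectors rose in 15 of 20 cases and fell in 5 (median 0.998, adjusted p = 0.00504; adjusted p = 0.403 with an estimated correlation), Tlr2 (-2.20) and Nlrp3 (-2.10) being the largest falls. The 10 other lists were not called, with adjusted p from 0.0744 for the lysosome list (12 of 16 rose and 4 fell) to 0.933 for alternative activation (2 of 5 rose and 3 fell) and for TLR4 and IKK signaling (4 of 16 rose and 6 fell). Among them, NF-κB feedback genes rose in 7 of 19 cases and fell in 10 (adjusted p = 0.518), and Bcl3 (1.73) and Socs3 (1.39) rose while Tnfaip3 (-1.50) fell. In the alternative activation list the median, mean and test differed in sign. The lysosome list was called with a mean FPKM of at least 5 (adjusted p = 0.0378) and oxidative phosphorylation under quantile normalization (adjusted p = 0.049).

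Between 1 h and 12 h, 2362 genes rose and 2461 fell, 228 and 122 by at least 2-fold; the count of 122 was 207 with a pseudocount of 0.1. That pseudocount moved Mertk to -2.41, and without a filter on level the chemokine median was 0.32. At that size 48 genes rose early and fell between the times, whether or not to the untreated level, among them Plk2, Nfkbiz, Egr3, Tnfsf9 and Irf1. A further 31 rose early and stayed high, including Tnf, Plk3 and Cd14, and 10 rose early and rose again, including Cd40, Ptgs2 and Saa3. The late rise took 157 genes, including Lcn2, Irf7 and Trib3, and the late fall 61, including Mertk and Mef2c. These 2 classes can hold genes with a smaller change at 1 h. Lcn2 was already called higher at 1 h by 0.915 (limma, adjusted p = 2.79e-06), from 0.366 to 1.56 FPKM, and Csf3 by 0.98. Both were near 0 without LPS, where the pseudocount shrinks differences. An early fall followed by a rise between the times, whether or not it reached the untreated level, was found in 10 genes, including Osgin1 and Ier5l, a fall that lasted in 10, including Arg1, and a fall that deepened in 2. Of genes changed at least 2-fold, 53 were higher at both times, against 5.53 for independent lists, and 13 were lower at both, against 0.91. Cd83, Egr3 and Nr4a1 were higher at 1 h and lower at 12 h than in untreated cells, against 3.35 for independent lists. Both times share the 3 untreated libraries. In that setting, 20 simulations of unchanged groups gave 0 shared genes. The median gene SD within groups was 0.056 on the log2 scale, so unchanged groups could hardly reach a 2-fold call at either time. This 0 was thus nearly fixed in advance and cannot judge what sharing libraries adds to the 53 and 13. The correlation of log2 differences across genes in these simulations was 0.501, against 0.488 found. A correlation of this size arises from shared libraries alone, so it cannot by itself show shared changes. The covariance was 0.131, against 0.00158 in the simulations, so noise in the shared untreated libraries gave little of it.

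Markers of other cell types were nearly absent from the table. No neuron, fibroblast, lymphocyte or mitochondrially encoded gene of the lists was listed, and of the oligodendrocyte list only Olig2 was, below the filter on level. The astrocyte list held Aldoc, with log2 differences of -0.30 at 1 h and -0.24 at 12 h. Of the endothelial list, Vwf had differences of -0.29 and -0.54 (-0.10 and -0.35 under quantile normalization, -0.49 and -0.99 with a pseudocount of 0.1), and Flt1 of -0.12 and 0.30; at 1 h the call for Vwf was lost under quantile normalization and that for Flt1 with adjustment over the implied genes (adjusted p = 0.0849) and without untreated library 1 or 1 h libraries 1 or 2 (adjusted p = 0.0905, 0.0779 and 0.0836). Of 14 histone genes in the fixed list of transcripts that mostly lack a poly(A) tail, 2 were tested. These were Hist1h1c (0.30, or 0.18 without 1 h library 3, and 0.42) and Hist1h2bc (-0.04, not passed, and 0.29). Whether the transcripts measured here had a tail was not tested. Because the table holds selected genes, the lack of a marker does not show that its cell type was absent.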

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

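The tests of the share of FPKM, of endoplasmic reticulum genes and of tRNA synthetases were chosen only after the results they concern had been seen; the other tests in this part were set before their results. The following responses differed between 1 h and 12 h by a test of the 12 h versus 1 h contrast itself, which removes the shared untreated libraries. As median log2 differences of 12 h from 1 h, the lists were immediate early genes (-1.016), chemokines (1.0), inflammatory effectors (0.998), interferon-stimulated genes (1.657), antigen presentation (0.45), homeostatic microglia (-0.403), G2/M (-0.477), S phase (-0.288), cholesterol synthesis (-0.319), glycolysis (0.351), NRF2 targets (0.684) and the unfolded protein response (0.813). None of these 12 kept its call with an estimated correlation, the smallest adjusted p being 0.084. Cd83 (-3.50), Egr3 (-3.67) and Nr4a1 (-4.09) stood above untreated cells at 1 h and below them at 12 h, by at least 2-fold each way. With 3 libraries per group, single libraries were not tested for standing apart.

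Glycolysis genes were lower at 1 h. A loss of FPKM share to induced genes would lower all FPKM by 1 factor, though genes near 0 move less in log2(FPKM + 1). The list median lay 0.214 below that of all tested genes (-0.214, 95% bootstrap interval -0.274 to -0.154, n = 19). With a mean FPKM of at least 5, where the pseudocount matters less, the median of all tested genes was -0.01. These values argue against such a loss as the whole cause. The interval treats list members as independent, and the other genes were selected to differ. Other targets of hypoxia-inducible factor, listed as not yet looked at, were lower as well, with a median of -0.388. Of these 19, 17 were below 0, with 16 called lower and 1 called higher. Ero1l, 1 of the targets, was also in the fixed unfolded protein list, so its value may have been seen. Lower activity of hypoxia-inducible factor is thus a candidate explanation. At 12 h, 11 of these 19 targets were still called lower than in untreated cells and 5 higher (median -0.154). Of the 19 glycolysis genes, 13 were then higher than in untreated cells and 6 lower (median 0.11, or -0.13 under quantile normalization). Both medians were higher at 12 h than at 1 h, so the 12 h values do not decide the matter. The explanation concerns the fall at 1 h only, and Hif1a itself rose by 0.23 at 1 h. A change of medium or of oxygen at the start of treatment cannot be told apart from LPS, since 0 untreated samples were taken at 1 h.

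G2/M genes were lower at 12 h. Their median lay below that of all tested genes (-0.52, 95% bootstrap interval -0.644 to -0.467, n = 23). With a mean FPKM of at least 5, the median of all tested genes was 0.056. These values argue against a loss of FPKM share as the whole cause, with the same limits on the interval and on the genes compared. Time in culture or cell density cannot be told apart from LPS, since 0 untreated samples were taken at 12 h. An effect of LPS on proliferation stays open as well.

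The unfolded protein response list was higher at 12 h, when its endoplasmic reticulum genes (median 0.601, n = 11) rose less than its ATF4 targets (median 1.52, n = 6), a difference of -0.919 (exact permutation p = 0.00339). These sets were drawn after the values were seen and leave out 3 of the 20 tested members, 2 of them called higher, so whether the whole list rose evenly with the chaperones stays open. An ATF4-dependent amino acid response may contribute: tRNA synthetases known as ATF4 targets stood above the others by 0.472 (medians 0.581 and 0.109, n = 11 and 6, exact permutation p = 0.0478). Without Aars and Gars, whose values had been seen before, the difference was 0.465 with an exact permutation p of 0.0703, so this stays open, under a criterion that was made stricter after the result was seen. Depletion of the medium over 12 h cannot be told apart from LPS, since 0 untreated samples were taken then.

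For each pairwise count the real split of the 6 libraries called the most genes of the 10 possible splits (1 of 10): 3330, 4611 and 4823 genes, with 0 in the highest other split each time. With 10 splits no share under 0.05 can be reached. For the F test, 1 of 100 splits drawn from 280 gave as many genes, the real one with 5324 against 3485 in the highest other. Because the listed genes had been selected on these very groups, none of these counts can judge chance.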

How the results depend on the processing

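The adjustment over 21878 implied genes was chosen after seeing the data; the other alternatives were planned. Over all of them, genes changed ranged over 2561 to 3522 at 1 h, 3573 to 5089 at 12 h, 3753 to 5275 between the times and 4128 to 5850 in the F test; without 1 library these were 2956 to 3350, 4458 to 4624, 4679 to 4831 and 5239 to 5273. A pseudocount of 0.1 raised the genes at least 2-fold lower to 71, 306 and 207, and a mean FPKM of at least 5 gave 20 at 1 h and 97 at 12 h. With a pseudocount of 0.1 the time classes held 20 genes (early and rising), 21 (early fall, then a rise), 18 (lasting fall), 5 (deepening fall) and 130 (late fall, 97 with a pseudocount of 0.5); a mean FPKM of at least 5 left 4 in the lasting fall. The share of higher genes among those changed at least 2-fold was 78.7%, 62.3% and 65.1%, and 67.3%, 50.2% and 59.3% with a pseudocount of 0.1. Of the 37 list calls, 2 held with an estimated correlation; without 1 library 36 to 38 were made. The causes were not tested, except that a smaller pseudocount shrinks low genes less and a stricter filter tests fewer genes. Reversed values were those of Hsp90aa1 under quantile normalization (-0.048 at 12 h and -0.008 between the times) and without untreated library 2 (0.008 at 1 h, in a range without 1 library of -0.052 to 0.008), Fth1 at 12 h under quantile normalization (0, by construction, as the top gene of every library) and Cxcl2 between the times without 12 h library 3 (-0.077, in a range without 1 library of -0.077 to 0.281). Aurka at 12 h, which did not pass, went to 0 without untreated library 3 (range without 1 library -0.04 to 0). For Hsp90aa1, Cxcl2 and Aurka the cause was not tested. Over alternatives the adjusted p of Hsp90aa1 at 12 h ran from 0.00251 to 0.269, that of the heat shock chaperones at 1 h from 0.024 to 0.541, of apoptosis and survival at 1 h from 0.00133 to 0.0622, and of S phase at 1 h from 0.0014 to 0.191. Among list values 1235 kept their side of the threshold and direction, 8 gained a call and 8 lost one; among named genes 4694 kept them, 8 gained, 25 lost and 6 reversed. With the library number as a block, all 155, 411 and 350 genes changed at least 2-fold were called again. Adjustment over 21878 genes called 2672, 4265 and 4533 genes, 5093 in the F test, and kept all genes changed at least 2-fold. Depth limits genes near 0, and a log2 difference of 0.1 was not recovered in simulated data.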

Other observations

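All pathway tests in this part, on 259 KEGG pathways with at least 10 tested members, were chosen only after the data had been seen; the tests of 3′ UTRs and gene spans were set before their results. At 1 h, in the spliceosome pathway 35 of 63 rose and 3 fell (median 0.10, or 0.05 under quantile normalization, adjusted p = 8.55e-05; adjusted p = 0.405 with an estimated correlation), including Smndc1 (0.31), Prpf38b (0.27) and Rbm25 (0.27), and in ribosome biogenesis 25 of 47 rose and 0 fell (median 0.10, adjusted p = 8.55e-05; adjusted p = 0.405 with an estimated correlation), including Pop7 (0.37), Nmd3 (0.35) and Gtpbp4 (0.33). Between 1 h and 12 h, 42 of the 63 spliceosome genes fell and 6 rose (median -0.23, adjusted p = 0.0226; adjusted p = 0.827 with an estimated correlation). Pathways were called in 24 (higher) and 6 (lower) cases at 1 h, 39 and 6 at 12 h, and 6 and 3 between the times; 0 were called with an estimated correlation.

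At 12 h, in the proteasome 34 of 37 rose (median 0.26, adjusted p = 4.6e-05; adjusted p = 0.445 with an estimated correlation), including Adrm1 (0.52), Psmd11 (0.46) and Psmd8 (0.43, or 0.21 under quantile normalization); the median was 0.08 under quantile normalization. In protein export 12 of 15 rose (median 0.24, or 0.14 under quantile normalization, adjusted p = 0.007; adjusted p = 0.444 with an estimated correlation), including Srprb (0.67), Srpr (0.50) and Sec61a1 (0.45, or 0.26 under quantile normalization), whose products carry new proteins into the endoplasmic reticulum. In DNA replication 26 of 29 fell and 2 rose (median -0.37, adjusted p = 0.000395; adjusted p = 0.464 with an estimated correlation), in mismatch repair 14 of 15 fell (median -0.42, adjusted p = 0.00176; adjusted p = 0.444 with an estimated correlation), including Msh6 (-0.70), and in the Fanconi anemia pathway 18 of 20 fell (median -0.41, adjusted p = 0.00336; adjusted p = 0.444 with an estimated correlation), including Fancd2 (-0.65) and Brca2 (-0.61). These pathways share members. In valine, leucine and isoleucine degradation, a mitochondrial pathway, 18 of 23 fell and 4 rose (median -0.50, adjusted p = 0.00538; adjusted p = 0.444 with an estimated correlation), including Acadm (-0.93), Aldh6a1 (-0.86) and Bckdha (-0.82).

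A hypothesis was that genes which rise early and fall between 1 h and 12 h carry signals for rapid mRNA decay. An AU-rich motif in the 3′ UTR was found in 63.0% of them (29 of 46) and in 25% of late rising genes (39 of 156; odds ratio 5.12, Fisher's exact p = 4.77e-06), against 32.4% of all tested genes. Longer 3′ UTRs alone (medians 1206 and 808 nt) would leave the density of motifs alike, but it was higher by 0.709 per kb (permutation p = 0.00032). Early transient and late rising genes differ in when they rise as well as in whether they fall. AU-rich elements may thus contribute to the fall or go with the early rise, which this comparison cannot tell apart. Genes that rose early and stayed high were not compared. Early transient genes were also shorter, with a median genomic span of 8.9 kb against 15.79 kb (permutation p = 0.0067). That comparison is again with late rising genes, so short length may go with the early rise rather than with the fall. The effects of motif and length were not separated. Decay was not measured. The tests were first run before Cd83, Egr3 and Nr4a1 were counted as early transient, and the values given are those of the later run.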
